A study of Arabidopsis thaliana with 5 samples.

How the data were processed

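RNA was sequenced from leaf epidermal protoplasts of Arabidopsis thaliana seedlings 9 days post germination, 3 libraries from wild type (WT) and 2 from hdl, a mutant of the homeodomain-like gene HDL. Per the labels' protocols, cells carrying a red membrane reporter under the ATML1 promoter, which is active in the epidermis, were collected by fluorescence-activated sorting, about 20000 per sample, and TruSeq RNA libraries were made from 10 to 20 ng of RNA. All 5 libraries carry batch number 1. The labels do not say whether replicates came from separate plantings, so p-values measure only the spread between these samples, which may be technical.

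Per the submitters' processing notes, the genome build was TAIR10 and the tools included FastQC 0.11.9, Trimmomatic 0.33, Bowtie2 2.5.0, SAMtools 1.16.1, deepTools and DESeq2; the role of each tool and the program that counted reads per gene are not given in the sources used here. The authors deposited a gene table of 24200 genes whose values are a normalized signal, named in the file as DESeq2-normalized counts. They also deposited raw counts for 3903 other features with 5 summary rows, in the layout of htseq output. None of the 3903 features is in the gene table, and 3901 of them are pseudogenes in the annotation, many derived from transposons. Gene names and coordinates come from the NCBI annotation of TAIR10.1, in which 24108 of the 24200 identifiers were found. The level of HDL itself was not analysed here.

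The fixed design foresaw a count test only if a raw count table covered all genes, so the normalized signal was tested with limma 3.58.1 in R 4.3.3. The test used log2(value + 1), an intensity trend, no covariate, all 5 libraries, and genes with at least 10 normalized counts in at least 2 libraries. Adjusted p-values are Benjamini-Hochberg values from this fit unless another tool is named, and a gene was called at an adjusted p under 0.05. Fold changes on this scale are uncertain for low genes: the pseudocount shrinks them, and a library at or near 0 can pull the mean of logs away from the ratio of the means. Within each library 100% of the values were whole multiples of a single step within 0.01, so whole reads were recovered by division. They totalled 18929251, 15418154 and 22838239 in WT replicates 1, 2 and 3, and 18316092 and 19741801 in hdl replicates 1 and 2. edgeR 4.0.16 and DESeq2 1.42.0 were run on these reads as alternatives. A floor of 3 counts, taken per library and covering counting error only, was used where every library of a group was at 0.

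The size factors of the deposited table match those recomputed from the recovered reads only if the counts of hdl replicate 1 were 2 per step. In the raw count table this library has an odd count in 0 of its 549 features above 0, whereas the other libraries have 423 to 585 features with odd counts. Its raw counts were therefore taken as 2 per read here; normalized values do not depend on this. For the raw count table, edgeR's quasi-likelihood test used the gene-table reads as library sizes, with hdl replicate 1 taken at 2 counts per read, and the TMM factors of the gene table. That scaling was chosen after the data were examined, when fits with other scalings had already been seen; every scaling that was run is given with the dependence on processing. Summary rows stayed out of all tests; reads with no feature made up 91.7 to 94.7% of the total of that table.

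A set of 22 gene lists with 292 genes was fixed before the data were examined, of which 289 are in the gene table. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. A further 4 lists with 43 genes were added after the data were examined. The genes named are ATML1, 9 stomatal and trichome regulators, and the 8 largest rises and 8 largest falls. The latter had to pass the threshold, have a mean of at least 50 normalized counts in the higher group, and have every hdl library beyond every WT library. From each list up to 4 called members with the smallest p are named, or the 2 most abundant where none was called. Genes outside this rule are marked as such, and a gene that the rule names is not reported here.

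On a simulated gene table limma recovered 4.88% of 82 genes changed 2-fold and 72.9% of 85 genes changed 4-fold, with 4 false calls among 20040 unchanged genes. The simulation used 1 dispersion for all genes, held no outlying library and changed far fewer genes than were called in the data. These shares therefore do not give the power of the comparison reported here. On a simulated raw count table, also with 1 dispersion, edgeR recovered 0 of 17 features changed 4-fold and 1 of 19 changed 8-fold, so that test had very little power in that setting. Alternatives changed the tool, scaling, filter, pseudocount, threshold, libraries and replicate block. Genes that overlap a gene on the opposite strand are named as uncertain, since the sources used here do not state whether counting used strand, and members of near-identical families (RBCS, LHCB, small heat shock proteins, CDC20) may share reads. Figures were drawn with matplotlib 3.10.9.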

Results

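Transcript levels were measured in sorted leaf epidermal cells of WT (n = 3) and hdl (n = 2) seedlings, at 15418154 to 22838239 recovered gene reads per library. The comparison asks which transcripts differ between the sorted cells of WT and hdl. Of 20391 genes tested with limma, 1674 were higher and 917 lower in hdl. By camera at its preset correlation, the flavonoid list and the list of epidermal identity, cuticle and wax were higher in hdl, with 7 of 10 and 12 of 21 tested members rising. Heat shock, mitosis and stomatal lineage lists were lower, with 9 of 9, 8 of 16 and 6 of 24 members falling. With an estimated correlation 0 lists were higher and 0 lower. The adjusted p was then 0.428 and 0.385 for the first pair and 0.238, 0.228 and 0.318 for the others. For the mitosis and stomatal lineage lists the estimate was -0.0024 and -0.0118, below the preset 0.01. Gene correlation therefore does not account for their higher adjusted p. With fry the adjusted p was 0.0278 and 0.0137 for the first pair and 0.00373, 0.00417 and 0.0137 for the others.

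These counts rest on few libraries. Without hdl replicate 1, no gene was called by limma, with 0 higher and 0 lower, when the lone hdl library was assumed to vary like the WT libraries. With the libraries scaled to equal totals, 994 genes were higher and 2553 lower, because the normalized counts summed to 24548412 ± 227670 in hdl (SD, n = 2) and 19625532 ± 527832 in WT (SD, n = 3). That scaling moved the median change of all genes from -0.05 to -0.37. Of the called genes tested in each alternative fit, which were 1862 without genes that overlap the opposite strand and 2565 to 2591 in the others, 0 changed sign. All 2591 called genes had every hdl library beyond every WT library. Leaving out a library, or changing the filter, gene set, pseudocount or replicate block, therefore could not turn a sign. Only other scalings and tools could have done so.

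The libraries of a genotype were not equally close. Pearson's r across genes, which are not independent replicates, was 0.973 between WT replicates 1 and 3, 0.914 and 0.915 between WT replicate 2 and these, and 0.917 between the hdl libraries. hdl replicate 2 was about as close to WT, at 0.922, 0.875 and 0.915 with WT replicates 1, 2 and 3, while hdl replicate 1 was at 0.866, 0.822 and 0.859. Without genes that overlap the opposite strand the hdl libraries were at 0.948, hdl replicate 2 and WT at 0.919, 0.872 and 0.912, and hdl replicate 1 and WT at 0.894, 0.852 and 0.887. The first principal component held 57.5% of the variance and placed hdl replicate 1 at 150, hdl replicate 2 at 38.8 and the WT libraries between -79.0 and -51.2. Of the 20391 tested genes, 10936 had every hdl library beyond every WT library. The chance share for a single gene is 20.0% for 3 against 2 libraries. Genes are not independent and can shift together in a library, so the excess was not taken as a test.

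In hdl replicate 1, 239 genes lay below 5% of their lowest value in the other libraries, among 15974 genes with at least 40 normalized counts in each of those. WT replicate 2 had 11 such genes and each other library had 0. Of the 238 found in the annotation, 81.1% overlap a gene on the opposite strand, against 29.9% of the other genes. Values of such genes in hdl replicate 1 were therefore read with this limit. Restricting the test to genes without such an overlap gave 1460 higher and 774 lower.

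**Figure D1:**
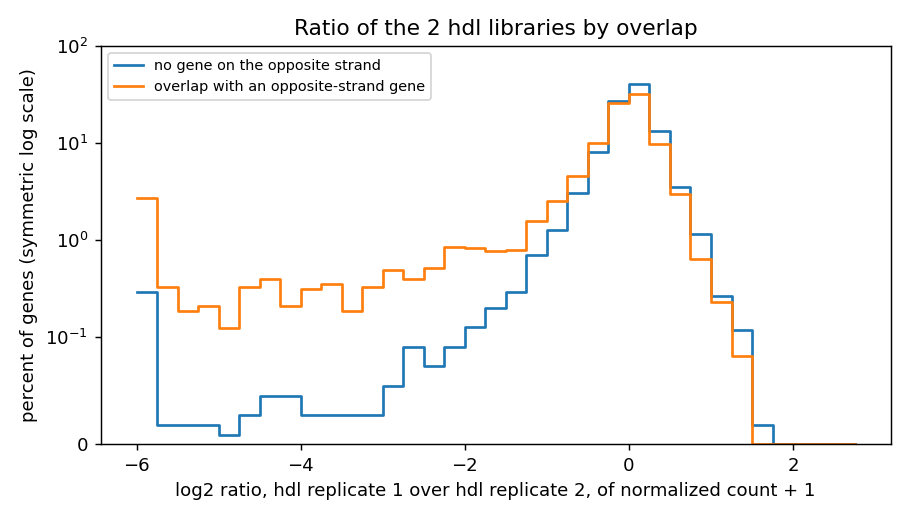
Distribution of the log2 ratio of hdl replicate 1 to hdl replicate 2 (normalized count + 1) for genes with and without an overlapping gene on the opposite strand, as percent of genes on a symmetric log scale; ratios beyond the axis are collected in the end bins. Genes with an opposite-strand overlap have the longer tail toward low ratios.

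Heat shock genes were lower in hdl. All 9 tested members fell, also when adjusted over the list alone (9 of 9), with log2 changes between -3.61 and -1.76 (camera adjusted p = 3.06e-09; adjusted p = 0.238 with an estimated correlation). HSP101, a protein disaggregase (AT1G74310, TAIR10.1 chromosome 1, 27936508 to 27940369, minus strand), had 21584 ± 3954 normalized counts in WT (SD, n = 3) and 4201 ± 195 in hdl (SD, n = 2), a log2 change of -2.35 ± 0.19 (SE, adjusted p = 0.00435). The heat shock factor gene HSFA2 (AT2G26150, chromosome 2, 11135624 to 11137792) changed by -1.97 ± 0.15 (adjusted p = 0.0043). HSP17.6A changed by -2.29 and HSP17.4 by -1.83. HSP101 and HSP17.4 overlap an opposite-strand gene.

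Flavonoid and anthocyanin genes were higher in hdl. Of 10 tested members 7 rose and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 2.78e-07; adjusted p = 0.428 with an estimated correlation). F3H, encoding flavanone 3-hydroxylase (AT3G51240, chromosome 3, 19025192 to 19026872), had 368 ± 130 normalized counts in WT (SD, n = 3) and 4315 ± 423 in hdl (SD, n = 2), a log2 change of 3.62 ± 0.33 (SE, adjusted p = 0.00504). CHS, encoding chalcone synthase, the first enzyme of the pathway, changed by 2.90, CHI by 3.03 and DFR by 3.36. F3H and CHS overlap an opposite-strand gene.

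The list of epidermal identity, cuticle and wax was higher in hdl by camera, and its parts were not tested apart. Of 21 tested members 12 rose and 0 fell; adjusted over the list alone, 13 rose and 1 fell (camera adjusted p = 3.52e-06; adjusted p = 0.385 with an estimated correlation). LTP1, a lipid transfer protein gene (AT2G38540, chromosome 2, 16130290 to 16131240), had 6088 ± 1748 normalized counts in WT (SD, n = 3) and 29182 ± 2489 in hdl (SD, n = 2), a log2 change of 2.30 ± 0.27 (SE, adjusted p = 0.00779). CER6, which elongates wax precursors, changed by 1.80, CER3, a wax synthesis gene, by 1.92, and LACS2, which acts in cutin synthesis, by 1.65. CER1 at 1.22 (adjusted p = 0.369), GPAT8 at 0.59 (adjusted p = 0.059) and MYB16 at 0.74 (adjusted p = 0.282), chosen after their values were seen, did not pass. ATML1, the source of the promoter used for sorting (AT4G21750, chromosome 4, 11555039 to 11560771), had 3104 ± 934 normalized counts in WT (SD, n = 3) and 3542 ± 28.0 in hdl (SD, n = 2) and did not pass (log2 change 0.23 ± 0.24, SE; adjusted p = 0.54). Without WT replicate 2 its change was 0.47 and passed (adjusted p = 0.00603), and with libraries scaled to equal totals it was -0.093. Of the other identity genes in the list, chosen after their values were seen, PDF2 rose by 0.87, while PDF1 at -0.21, ACR4 at 0.21, HDG1 at -0.26, HDG12 at -0.10 and HDG5 at -0.70 did not pass; HDG5 passed with edgeR (adjusted p = 0.0486), and HDG12 overlaps an opposite-strand gene.

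A minority of stomatal lineage regulators were called, all lower in hdl. Of 24 tested members 0 rose and 6 fell; adjusted over the list alone, 1 rose and 8 fell (camera adjusted p = 0.0217; adjusted p = 0.318 with an estimated correlation). FAMA, which acts in guard cell differentiation (AT3G24140, chromosome 3, 8715118 to 8718211), had 259 ± 84.8 normalized counts in WT (SD, n = 3) and 62.9 ± 8.85 in hdl (SD, n = 2), a log2 change of -1.98 ± 0.35 (SE, adjusted p = 0.0206). The receptor-like protein gene TMM (AT1G80080, chromosome 1, 30127819 to 30129649) changed by -1.40, BRXL2 by -1.47 and TCX2, which overlaps an opposite-strand gene, by -1.12. SPCH had a log2 change of -0.91 (adjusted p = 0.288), EPF2 of -3.69 (adjusted p = 0.0753), BASL of -2.79 (adjusted p = 0.169) and EPF1 of 0.28 (adjusted p = 0.919), none of which passed; the EPF1 value turned negative with edgeR and DESeq2, and EPF2 passed with DESeq2 (adjusted p = 0.017). MUTE lay below the filter, with means of 4.07 normalized counts in WT and 3.20 in hdl. Of 15 guard cell genes 1 rose, CYP86A2, a cutin synthesis gene, by 1.79, and 0 fell; adjusted over the list alone, 2 rose (camera adjusted p = 0.693). CYP86A2 overlaps an opposite-strand gene.

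None of 16 trichome genes was called by limma, over all genes or adjusted over the list alone (0 and 0; camera adjusted p = 0.34, and fry adjusted p = 0.0278 toward higher). GL1 had a log2 change of 2.87 (adjusted p = 0.192) and TTG1 of 0.23 (adjusted p = 0.45), which was 0.40 and passed without WT replicate 2 (adjusted p = 0.0252). GL2 (AT1G79840, chromosome 1, 30036956 to 30041440) overlaps an opposite-strand gene and had 107 normalized counts in hdl replicate 1, 1330 in hdl replicate 2 and 861 to 1320 in WT. Without hdl replicate 1 its log2 change of -1.51 became 0.30, and without hdl replicate 2 it was -3.32 and passed (adjusted p = 0.00415), so the value rests on hdl replicate 1. Of 11 pavement cell genes 1 rose and 2 fell; adjusted over the list alone, 1 rose and 5 fell (camera adjusted p = 0.0342; adjusted p = 0.412 with an estimated correlation). LNG1 changed by -1.44, RIC4 by -1.20 and LNG2 by 0.68; LNG1 and LNG2 overlap an opposite-strand gene.

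**Figure D2:**
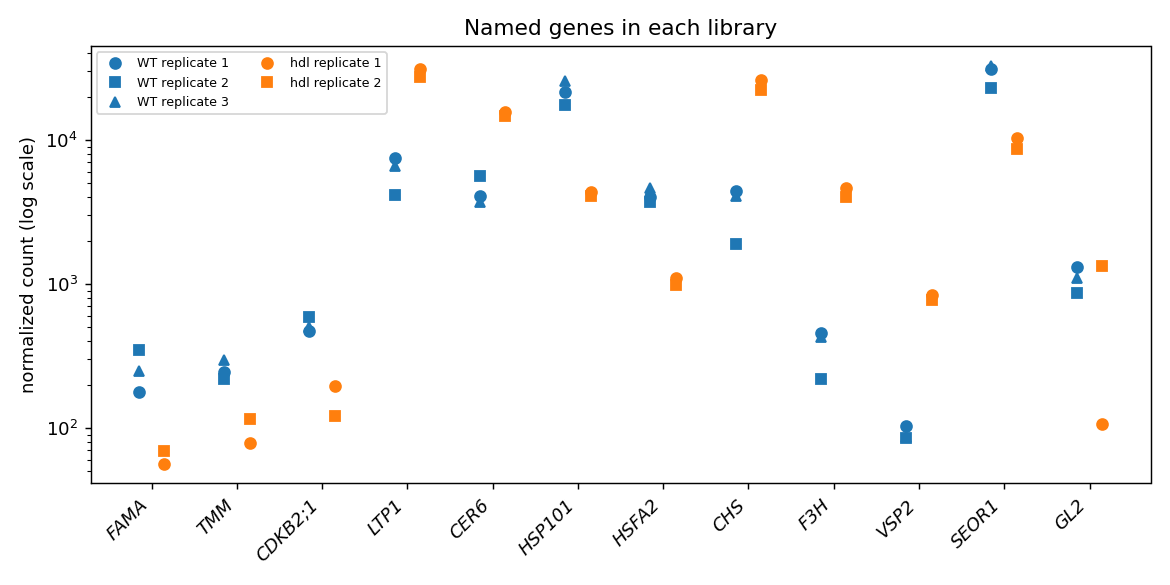
Normalized counts on a log scale of 12 named genes in each of the 3 WT (blue) and 2 hdl (orange) libraries, with the marker shape giving the replicate number. For GL2 the hdl libraries lie at 107 and 1330, whereas for HSP101 they lie at 4339 and 4063, below every WT library.

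Mitotic genes were lower in hdl. Of 16 G2 and mitosis genes 0 rose and 8 fell, and 15 fell when adjusted over the list alone (camera adjusted p = 5.59e-07; adjusted p = 0.228 with an estimated correlation). CDKB2;1, a mitotic cyclin-dependent kinase gene (AT1G76540, chromosome 1, 28720328 to 28722550), had 522 ± 63.2 normalized counts in WT (SD, n = 3) and 159 ± 53.7 in hdl (SD, n = 2), a log2 change of -1.74 ± 0.26 (SE, adjusted p = 0.0141). CDKB2;2 changed by -1.35, CYCA2;3 by -1.23 and PLE, a microtubule-associated protein gene, by -1.14; all but PLE overlap an opposite-strand gene. None of 11 S phase genes was called by limma, over all genes or adjusted over the list alone (0 and 0; camera adjusted p = 0.594), with PCNA2 at -0.16 (adjusted p = 0.6) and MCM7 at 0.10 (adjusted p = 0.798), both of which overlap an opposite-strand gene. Of 9 D-type cyclin, inhibitor and endocycle genes 1 rose and 1 fell; adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.34, and fry adjusted p = 0.0278 toward lower). CYCD3;1, a D-type cyclin gene, changed by -1.15 and SMR1, a cell cycle inhibitor gene that overlaps an opposite-strand gene, by 1.11.

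Markers of other cell types moved in different directions, and some were abundant in the sorted cells. In WT, RBCS2B had a mean of 30924 normalized counts and XCP2 of 23912, against 3104 for ATML1. The purity of the sorted cells was not tested. A change within epidermal cells therefore cannot be told apart from a difference in cell mix, here or for the other lists. Of 15 mesophyll and photosynthesis markers 2 rose and 0 fell, and 5 rose when adjusted over the list alone (camera adjusted p = 0.00136; adjusted p = 0.528 with an estimated correlation). GAPA1 changed by 1.18 and RBCS2B, which may share reads with other RBCS genes, by 0.98. Of 13 vascular markers 0 rose and 4 fell, and 5 fell when adjusted over the list alone (camera adjusted p = 0.0289; adjusted p = 0.676 with an estimated correlation; fry adjusted p = 0.121). SEOR1, a sieve element gene, had 28955 ± 5148 normalized counts in WT (SD, n = 3) and 9519 ± 1166 in hdl (SD, n = 2), a log2 change of -1.59 ± 0.21 (SE, adjusted p = 0.00986). XCP2 changed by -1.59, ATHB15 by -1.42 and APL by -1.35. SULTR2;2 at 0.51, SWEET11 at 0.46, SUC2 at 0.39 and SWEET12 at 0.06, chosen after their values were seen, did not pass; SULTR2;2 overlaps an opposite-strand gene.

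No gene of either chromatin list was called. None of 15 Polycomb and H3K27 demethylase genes (camera adjusted p = 0.683) and none of 16 remodeller and histone modifier genes (camera adjusted p = 0.813) was called by limma, over all genes or adjusted over the list alone (0 and 0). JMJ13 had a log2 change of 0.39 (adjusted p = 0.0963), ELF6 of -0.29 (adjusted p = 0.239), SYD of -0.06 (adjusted p = 0.795) and BRM a mean of 3868 normalized counts in WT and 3860 in hdl (adjusted p = 0.99). JMJ13, ELF6 and BRM overlap an opposite-strand gene, as do 8 of the 15 Polycomb and demethylase genes. JMJ13 passed without WT replicate 2 (adjusted p = 0.0267) and ELF6 with libraries scaled to equal totals (adjusted p = 0.0426). Of 8 textbook Polycomb targets above the filter 0 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0526; adjusted p = 0.528 with an estimated correlation). The list's median was -1.91 in limma and -1.10 with DESeq2, and the list passed with camera on ranks (adjusted p = 0.0404) and without hdl replicate 2 (adjusted p = 0.01). Without hdl replicate 1 the median was -0.77 (adjusted p = 0.199). Of the 8 genes 3 overlap an opposite-strand gene, among them SHP1, chosen after its values were seen, with 0 normalized counts in hdl replicate 1, 60.5 in hdl replicate 2 and 41.4 to 64.1 in WT, so the median rests in part on hdl replicate 1. Without such genes it was -1.24 (adjusted p = 0.0747). The called gene was SEP3, a floral gene, at -1.01, which did not pass with edgeR (adjusted p = 0.0501).

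Stress and hormone lists were mixed. Of 10 wound and early stress genes 4 rose and 0 fell, and 7 rose when adjusted over the list alone (camera adjusted p = 0.000403; adjusted p = 0.238 with an estimated correlation). VSP2, a jasmonate-responsive storage protein gene, had 92.2 ± 10.2 normalized counts in WT (SD, n = 3) and 803 ± 43.6 in hdl (SD, n = 2), a log2 change of 3.11 ± 0.22 (SE, adjusted p = 0.00343); VSP1 changed by 3.05, ZAT10 by 0.87 and WRKY53, which overlaps an opposite-strand gene, by 0.86. Of 6 pathogen response genes 1 rose, PR5 by 1.77, and 0 fell; adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.683), and the list's median of 0.00 lay just below 0 while its mean of 0.05 and the test pointed higher. Of 9 auxin genes 1 rose and 3 fell; adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.813), with a median of 0.14 and a mean of -0.24. GH3.3 changed by -1.77, AUX1 by -0.58 and PIN3 by 0.89. Of 12 leaf polarity genes 1 rose and 2 fell; adjusted over the list alone, 2 rose and 4 fell (camera adjusted p = 0.774, toward lower, with a median of 0.07 and a mean of 0.02). REV, which overlaps an opposite-strand gene, changed by -0.92, PHV by -0.90 and YAB3 by 0.84.

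None of 6 cytokinin response genes (camera adjusted p = 0.539) and none of 10 glucosinolate genes (camera adjusted p = 0.0595) was called by limma, over all genes or adjusted over the list alone (0 and 0). ARR4 had a log2 change of -0.46 (adjusted p = 0.338), ARR7 of -0.27 (adjusted p = 0.47), MAM1 of 0.49 (adjusted p = 0.559) and SUR1 of 0.49 (adjusted p = 0.345). ARR4 passed without WT replicate 2 (-0.76, adjusted p = 0.00888), and the glucosinolate list passed toward higher in 7 alternatives, at adjusted p-values from 0.00229 to 0.0465. That list did not pass with an estimated correlation (adjusted p = 0.723) or with fry (adjusted p = 0.406). Of 8 reference genes 1 rose, ACT2 by 0.76, also when adjusted over the list alone (camera adjusted p = 0.289).

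**Figure D3:**
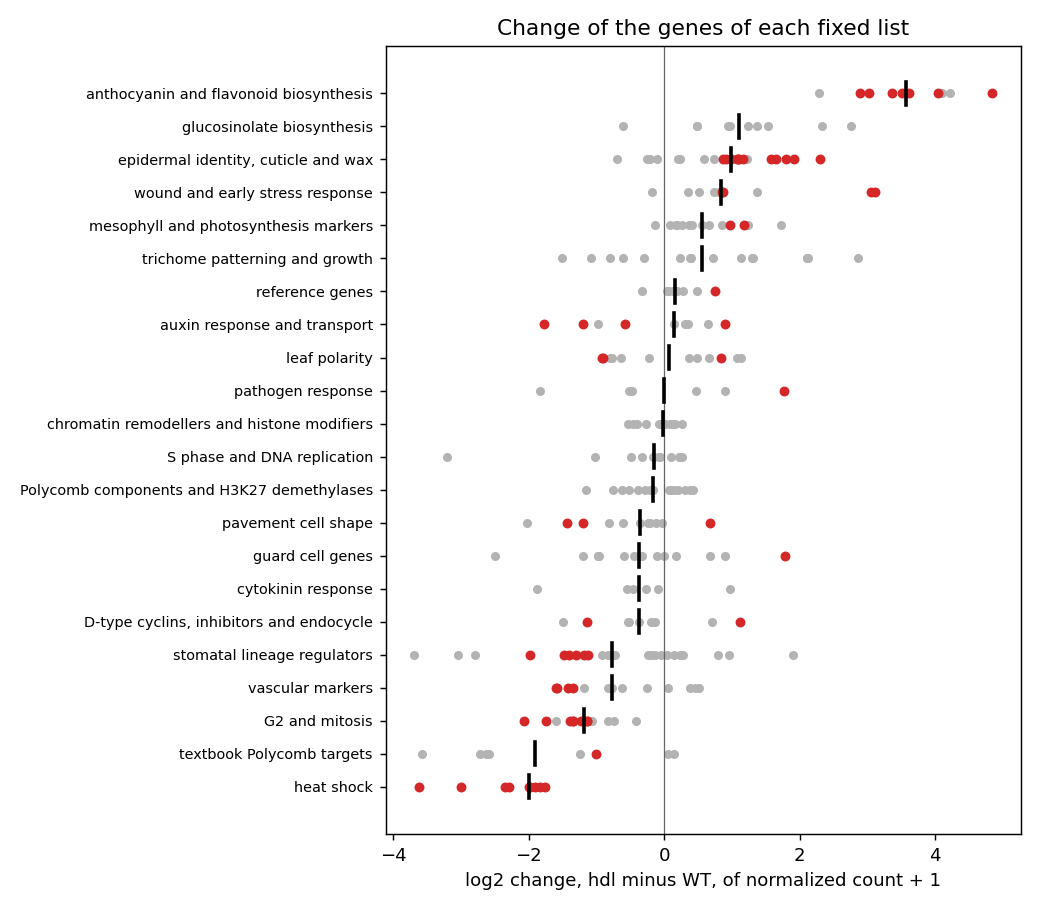
Log2 change (hdl minus WT, normalized count + 1) of each tested gene of the 22 fixed lists, ordered by median. Red points passed an adjusted p of 0.05 in limma, grey points did not, and black bars are list medians; the heat shock median is -2.002 and the flavonoid median 3.56.

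The largest rises included AT2G15555 (chromosome 2, 6785904 to 6786976), at 0 in every WT library and 302 ± 74.2 normalized counts in hdl (SD, n = 2), at least 95.1-fold higher against a floor of 3 counts per WT library. LEA3, a late embryogenesis abundant protein gene (AT1G02820, chromosome 1, 623656 to 624567), had 42.3 ± 14.8 normalized counts in WT (SD, n = 3) and 2051 ± 20.9 in hdl (SD, n = 2), a log2 change of 5.62 ± 0.32 (SE, adjusted p = 0.00298). AT2G27420 changed by 6.95, UGT73C1 by 5.51, SQP1 by 5.27, AT1G65870 by 5.18, UF3GT by 4.83 and AT5G24155 by 4.69.

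The largest falls were AT5G24240 at -6.58, MRD1 at -6.18, AT2G16586 at -4.71, ABCG16 at -4.45, AT5G10880 at -4.36, AT5G04238 at -4.31, AO4 at -4.17 and AT4G21300 at -3.98. AT5G24240, MRD1, AT5G10880, AT5G04238 and AT4G21300 overlap an opposite-strand gene. In the order of the falls, the values of all 8 genes were 0, 0, 0, 0, 1.35, 0, 1.35 and 9.44 normalized counts in hdl replicate 1. In hdl replicate 2 they were 4.94, 17.3, 6.18, 11.1, 28.4, 9.88, 3.71 and 58.1. With edgeR, ABCG16 (adjusted p = 0.0687), AT5G10880 (adjusted p = 0.0519) and AT5G04238 (adjusted p = 0.074) did not pass.

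In the raw count table, 187 features were tested. No feature was called by edgeR, with 0 higher and 0 lower, while 3 were higher and 29 lower at an unadjusted p under 0.05. That imbalance depends on the scaling, which was chosen after other fits had been seen. TMM on the table itself gave 13 higher and 10 lower, the table's own totals 4 and 9, and hdl replicate 1 not doubled 4 and 4. The not-doubled fit sets 2 counts per read against a library size at 1 per read, and the own totals may do so too. Halving the counts of hdl replicate 1 instead gave 3 higher and 28 lower. The dependence on scaling is therefore read from TMM on the table. DESeq2 on the same features called 3 higher and 1 lower, and DESeq2 on 1724 unfiltered features called 0 higher and 1 lower. Without hdl replicate 2, 3 features were higher and 38 lower, and without hdl replicate 1, 2 were higher and 14 lower. By the rule used for genes, applied here after the data were examined, hdl replicate 1 was near 0 in 8 of 76 features and each other library in 0. All 8 are among the 38 lower features, and 4 of them overlap an opposite-strand gene. AT2G11240, chosen after its values were seen and overlapping such a gene, had 2 counts in hdl replicate 1 and 1571 in hdl replicate 2; AT2G06045, chosen likewise and with no overlap, had 2 and 695. The rule passes over features below 40 counts in any other library. Among these, chosen after their values were seen, AT5G13205 had 0 counts in hdl replicate 1 and 63 in hdl replicate 2. AT3G02515 had 0 and 37. Both are among the lower features. The lower calls and totals are read with these limits. The summed counts of the table were 1920 ± 107 CPM of the gene reads in WT (SD, n = 3) and 1289 ± 179 in hdl (SD, n = 2; exact two-sided permutation p = 0.1, the smallest that 10 splits allow). Without the 8 features they were 1561 to 1672 CPM in WT, 1162 in hdl replicate 1 and 1244 in hdl replicate 2. Smaller features at 0 in hdl replicate 1 remain in these sums. As a share of that table's own total they were 0.0959% ± 0.00647 in WT (SD, n = 3) and 0.0757% ± 0.0245 in hdl (SD, n = 2; exact two-sided permutation p = 0.2). By this measure hdl replicate 2 was at 0.0584%, hdl replicate 1 at 0.0930% and the WT libraries at 0.0885 to 0.101%. Whether the total of hdl replicate 1 also holds 2 counts per read was not established. That total, 40183058, lay within the WT range of 34162475 to 49433695, as did its recovered gene reads at 1 per step. If only its feature counts are doubled, its share is too high. The share and its permutation p therefore do not show which hdl library the lower mean rests on.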

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

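Alternatives that removed genes with an opposite-strand overlap, scaled to equal totals or doubled hdl replicate 1, and all alternatives for the raw count table, were chosen after the data were examined. Genes higher and lower in hdl were 1674 and 917. DESeq2 gave 2510 and 2013, and an FDR under 0.01 gave 340 and 96. Scaling to equal totals gave 994 and 2553, with 28.0% of calls higher against 64.6%. edgeR with upper-quartile scaling put 53.4% of its calls higher and DESeq2 55.5%. Leaving out 1 library gave 0 to 3574 higher and 0 to 2295 lower: 791 and 189 without WT replicate 1, 3574 and 2295 without WT replicate 2, 358 and 69 without WT replicate 3, 0 and 0 without hdl replicate 1, 528 and 1119 without hdl replicate 2. Where 1 hdl library is left it is assumed to vary like WT. List genes higher and lower were 32 and 36; DESeq2 gave 50 and 56, an FDR under 0.01 gave 11 and 13, equal totals gave 62 lower, and leaving out 1 library gave 0 to 67 and 0 to 60. Lists higher and lower were 4 and 5. An estimated correlation gave 0 and 0, fry and camera on ranks each gave 5 and 5, and leaving out 1 WT library gave 4 to 5 and 3 to 5. With fry the trichome and D-type cyclin lists passed in addition, and the vascular list did not pass. The cause was not tested.

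With the replicate block, 0 genes were higher and 0 lower, and 0 and 0 list genes, with fewer residual degrees of freedom by construction. Deviations of same-numbered libraries correlated at 0.00477 and -0.0123, so the numbers are not known to pair samples. In the raw count table, where 0 were called either way, dropping the filter gave 1 higher and 14 lower, DESeq2 0 and 1 without the filter and 3 and 1 with it, and leaving out 1 library 0 to 3 higher and 0 to 38 lower. Library sizes from the table's own total, TMM on the table, hdl replicate 1 not doubled and its counts halved each called 0; at an unadjusted p under 0.05 they gave 4, 13, 4 and 3 higher and 9, 10, 4 and 28 lower.

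Over all alternatives, thresholds included, the named genes' values kept sign and call in 1222 cases, lost the call in 314 and gained it in 7. Every called gene had all hdl libraries beyond all WT libraries, so leaving out a library could not turn its sign. Signs turned only for lists and genes that did not pass in the reported fit; of these GL2 passed without hdl replicate 2, and ATML1 and TTG1 without WT replicate 2. Scaling to equal totals gave leaf polarity -0.25, auxin -0.18, reference genes -0.17, ATML1 -0.093, TTG1 -0.092 and MCM7 -0.22. The replicate block gave S phase 0.052, remodellers 0.028, leaf polarity -0.016 and BRM 0.028. The pathogen list was 0.68 without a filter and 5.41e-05 with voom. EPF1 was -0.60 with DESeq2, -0.62 with edgeR TMM, -0.61 with RLE, -0.72 with upper quartile, -0.58 with hdl replicate 1 doubled and -0.11 with a pseudocount of 5; MCM7 was -0.043 with upper quartile. Leaving out 1 library gave S phase -0.40 to 0.052, Polycomb components -0.17 to 0.12, remodellers -0.037 to 0.028, leaf polarity -0.065 to 0.13, pathogen -0.030 to 0.11, EPF1 -1.15 to 1.18, GL2 -3.32 to 0.30, MCM7 -0.092 to 0.24, BRM -0.028 to 0.028, SYD -0.17 to 0.036 and MAM1 -0.093 to 0.79. The cause was not tested.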

Other observations

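The clock, photorespiration and nitrogen lists, and the tests of explanations in this part, were chosen after the data were examined; the mesophyll, wound and heat shock lists were fixed before. Of 10 clock genes that peak in the morning 3 rose and 0 fell, and of 10 that peak in the evening 0 rose and 3 fell, in limma. Adjusted over each list alone, 7 rose and 1 fell in the morning list, and 0 rose and 8 fell in the evening list. CCA1 rose from 1198 ± 463 normalized counts in WT (SD, n = 3) to 4839 ± 23.5 in hdl (SD, n = 2), RVE8 by 2.17 (adjusted p = 0.0391), LNK1 by 1.24 (adjusted p = 0.00809), ELF3 by -1.80 (adjusted p = 0.0159), LUX by -1.42 (adjusted p = 0.0194) and PRR5 by -1.58 (adjusted p = 0.0267). LNK1, ELF3 and LUX overlap an opposite-strand gene. The camera adjusted p was 0.00243 for the morning list and 3.7e-05 for the evening list, and 0.104 for each with an estimated correlation.

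Of 9 photorespiration genes 7 rose and 0 fell (camera adjusted p = 4.02e-07; adjusted p = 0.104 with an estimated correlation), among them CAT2 by 2.53 and GLDP1 by 2.40, both of which overlap an opposite-strand gene. Of 15 mesophyll and photosynthesis markers 2 rose and 0 fell, with a median of 0.56 (camera adjusted p = 0.00136; adjusted p = 0.528 with an estimated correlation). Of 11 nitrate and ammonium genes 8 rose and 0 fell (camera adjusted p = 1.47e-08; adjusted p = 0.104 with an estimated correlation), among them NPF6.4 by 4.35, AMT1;2 by 3.95 and CLC-A, which overlaps an opposite-strand gene, by 2.19. All of these genes were chosen after their values were seen.

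The 239 genes near 0 in hdl replicate 1 overlap an opposite-strand gene in 81.1% of the 238 annotated cases, against 29.9% of other genes, while overlaps on the same strand were 5.88% and 5.58%. The 186 opposite-strand partners examined were not themselves among these genes and had at least 40 normalized counts in each of the other libraries. Their median log2 ratio of hdl replicate 1 to hdl replicate 2 was 0.04. Partners near 0 were left out by that choice, so the value says nothing about them. The opposite-strand share argues against deleted or diverged sequence as the main source of these losses in that library (two-sided Fisher exact p = 4.99e-59). The test treats genes as independent, and it does not settle the question for genes without such an overlap. A gene with at least 17913 normalized counts elsewhere argues against lower depth. A candidate explanation is that reads were assigned by strand in hdl replicate 1 and not in the other 4 libraries. No biological explanation was tested, since the pattern lies within a genotype.

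For the clock genes, scaling is argued against, since the morning median stayed at or above 0.39 and the evening median at or below -1.49 under the 7 scalings and tools run. Collection at another time of day cannot be told apart from an effect of the mutation, because no collection time was used here. That limit holds for every list compared here, among them the flavonoid, photosynthesis, photorespiration and nitrogen lists. The morning minus evening index was 1.15, 0.07 and 1.38 in the WT libraries, a range of 1.31 log2 units, and 3.77 and 3.31 in hdl. A clock difference due to the genotype stays open and untested.

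For the lower heat shock genes, a handling stress lowered for both lists is argued against by the wound and early stress list, whose median was 0.84 with 0 members falling. A handling difference that moved the lists in different ways was not tested and stays open. Scaling is argued against by the heat shock median, which was nearest to 0 at -2.002. Collection at another time of day cannot be told apart from the mutation: WT replicate 2, the WT library farthest in the clock index, differed from the other WT libraries by -0.16 log2 units in its heat shock mean, but it is a single library. A heat response difference due to the genotype stays open and untested.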
